A study of Mus musculus with 4 samples.

How the data were processed

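RNA from the telencephalon, the part of the embryonic brain that forms the cerebral hemispheres, was compared between 152F7 mice and wild-type mice at embryonic day 12.5. The 152F7 line carries a yeast artificial chromosome with a piece of the human Down syndrome region that includes DYRK1A, a gene for a protein kinase. Both genotypes were on the FVB background, per the labels. The labels call the arrays technical replicates, and the series text speaks of dependent measurements of one series of pooled samples, so each genotype was treated as 1 RNA pool. Total RNA was extracted with Trizol, and 1 ug was amplified and labelled with Cy3 or Cy5, per the labels' protocols. The labelled pools were hybridised together on 4 Agilent whole mouse genome arrays with 60-mer probes. On 2 arrays the wild-type pool carried Cy5 and on the other 2 arrays the 152F7 pool carried Cy5.

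The deposited table gives 1 value per spot and array for 44290 spots. These deposited values are log ratios of the array's 2 channels, and they were read as log2. The scanner software, background correction, normalization, log base, direction and filter are not given in the sources used here. The largest value has a size of 5.76, above the 4.82 that a log10 ratio of raw intensities can reach on a 16-bit scanner. This argues against log10 but does not exclude it, since background correction and normalization are unknown. Natural logs were run as an alternative. Every fold below assumes log2. The medians of the 4 arrays lie between -0.007 and 0.007, so the values were centred before deposit or needed no centring. A value is present for 28942 spots (65.3%) and 27309 spots (61.7%) on the arrays with wild type in Cy5, and for 27483 spots (62.1%) and 23796 spots (53.7%) on those with 152F7 in Cy5. Intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

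The direction of the ratio was settled in part, and only after the values had been seen. The plan took the ratio as 152F7 over wild type with the dye-swapped arrays turned. If each value were Cy5 over Cy3, turning 1 orientation should bring out the genotypes, and different probes of one gene should then give like values. Over 4352 genes with at least 2 probes, Xist left out, the Pearson correlation across genes between a gene's probes was 0.0973 in the turned mean (95% bootstrap interval 0.0634 to 0.134) and 0.421 in the mean of the values as deposited (0.373 to 0.468). The contrasts between replicate numbers, which hold neither genotype nor dye, gave 0.0707 and 0.0509. The deposited ratios were therefore read as running the same way on all 4 arrays, and the results are the unturned means. Which genotype is the numerator is not settled by the labels or the values. The text says numerator pool and denominator pool, of which 1 is 152F7 and the other wild type. The turned reading, which was the planned one, is kept as an alternative.

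Over all spots with values on all arrays, arrays of the same orientation correlated at 0.905 and 0.862 and arrays of opposite orientation at -0.596 to -0.661 (Pearson, across spots, which are not independent replicates). Over spots with a gene symbol, the Spearman correlations were 0.632 and 0.613 for the same orientation and -0.0878 to -0.162 for opposite ones, and the Pearson correlations were 0.726 and 0.648 for the same orientation and 0.0367 to 0.116 for opposite ones. Dye effects cancel in the mean of both orientations.

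Probes were named through the platform annotation by spot number, with symbols checked against the GRCm38.p6 gene table by Entrez identifier. Of the 44290 spots, 32042 have 1 gene symbol, 47 have several and 12201 have none in that annotation. Of the 32089 annotated spots, 31906 matched the gene table and 0 symbols differed. Spots with several symbols were not used. There were 20923 spots with values on all 4 arrays, of which 17767 have a symbol, and these give 11791 genes. A gene's value is the mean over its probes, and 4353 genes have more than 1.

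No test across genotypes was possible with 1 pool each, so no p-value is given. The SD over the 4 arrays covers labelling, hybridisation and the difference between dye orientations, which cancels in the mean. It leaves out the spread between embryos and between pools. A gene was counted as higher or lower where the mean ratio was at least 1.5-fold and had that direction on all 4 arrays, and the same rule was run on both contrasts of replicate number as a measure of noise. On simulated data of 11791 genes with the measured dye and replicate noise, the rule called 0 of 50 genes changed 1.25-fold, 23 of 50 changed 1.5-fold, 50 of 50 changed 2-fold, 50 of 50 changed 3-fold and 0 of 11591 unchanged genes. A looser threshold was set where the mean count of the noise contrasts is at most 5% of that of the pools, which was 0.085 on the log2 scale (1.06-fold), and counts within gene lists use it. The median of each of 45 gene lists was set against 10000 random lists of the same size and called outside where it lay beyond the 2.5th or 97.5th percentile.

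The lists, the rules for counting genes and for comparing lists and the rule for naming genes were fixed before the data were examined. The reading of the direction and the tests of explanations were added later. The rule takes Dyrk1a, Ttc3, Pigp, Vps26c and Kcnj6, up to 12 genes at each end past the 1.5-fold rule without clone or predicted names, and up to 4 members of each described list with the largest mean and the same sign on all 4 arrays. Alternatives changed the centring, the summary over arrays, the fold, the demand on direction, the handling of several probes, noisy probes and missing values, the orientation, the log base, the arrays left out and the matching of random lists. The turned reading, first planned as the main one, was made an alternative after seeing the data. Random lists matched on gene length in 20 bins were added after seeing the data and before the outcome of that matching was seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.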

Results

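The series asks which genes differ in expression between the telencephalon of 152F7 transgenic embryos and that of wild-type embryos of the same age. A pool of RNA from each genotype was hybridised on 4 two-colour arrays, 2 in each dye orientation. Values of genes are mean log2 ratios of the numerator pool over the denominator pool, with the SD over the 4 arrays (n = 4 technical arrays, 1 pool per genotype). For a gene list the value is the median of its members' means. The SD beside it is that of the list's medians on the 4 arrays, and so is not the spread around that value. The value can lie outside those array medians, as for the cell cycle inhibitors and the protocadherins. The genotype of the numerator pool is not settled, so a signed value says which pool was higher and not which genotype. That the ratios run one way on all arrays was concluded from the values themselves.

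**Figure D1:**
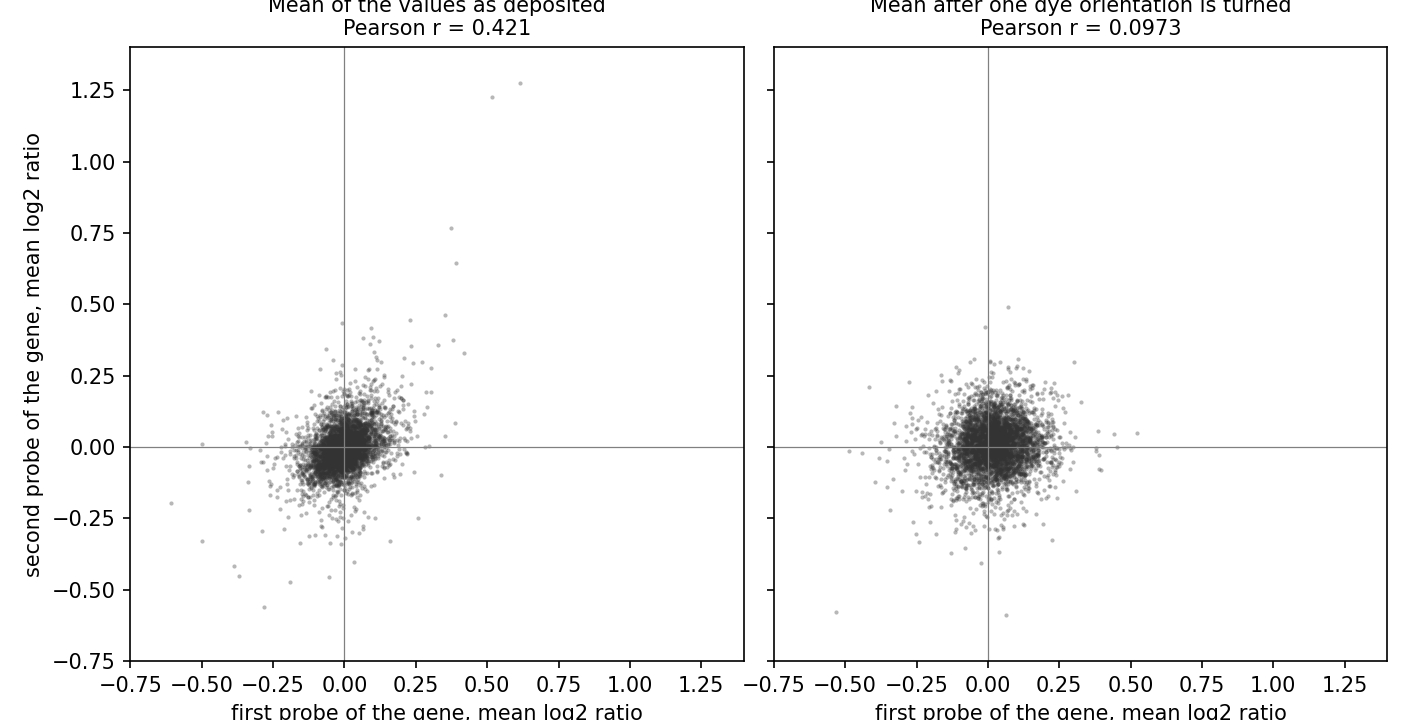
Mean log2 ratio of one probe of a gene (x axis) against another probe of the same gene (y axis), 1 point for each of 4352 genes. The probes correlate at 0.421 in the mean of the values as deposited (left) and at 0.0973 after 1 dye orientation is turned (right).

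Dyrk1a and its neighbours did not stand apart between the pools. Dyrk1a, which encodes the kinase for which the segment is best known, had a mean of 0.03 ± 0.13, with 3 probes that ranged from -0.006 to 0.05 and thus differed in direction. Its neighbours Ttc3, which encodes a ubiquitin ligase, and Pigp, which encodes an enzyme of GPI anchor synthesis, had means of 0.04 ± 0.28 and -0.07 ± 0.18. Vps26c, a subunit of the retriever complex of endosomes, had a mean of -0.01 ± 0.07. No probe of Kcnj6, a potassium channel gene, had values on all 4 arrays. Each of these means was smaller than its SD over the arrays. For Ttc3 that SD comes from the dye orientation, with -0.196 and -0.204 for wild type in Cy5 and 0.300 and 0.262 for 152F7 in Cy5. Dyrk1a and Pigp also split by orientation, so the SD is not the error of their means. The median of the 4 measured genes was 0.01, at the 62.2nd percentile of random lists. A mouse probe may or may not bind the human transcript. With 1 orientation turned, as if values were Cy5 over Cy3, the ratios of 152F7 over wild type would be 0.10 for Dyrk1a, 0.24 for Ttc3, 0.15 for Pigp and 0.01 for Vps26c, all above 0, and their median of 0.12 would lie at the 99.7th percentile of random lists.

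Few genes differed between the pools by 1.5-fold or more, and most of these belonged to the sex chromosomes or the lens of the eye. Of 11791 genes, 9 were higher in the numerator pool and 1 was lower, and both noise contrasts gave 0. The lower count was 6 without replicate 2 of 152F7 in Cy5, and the orientation with 152F7 in Cy5 alone gave 14 higher and 12 lower. Xist, the RNA that silences an X chromosome in female cells, was lowest at -3.38 ± 0.11, 10.4-fold higher in the denominator pool, but its 3 probes differed widely, with means of -1.06, -3.61 and -5.46. The Y-linked genes Eif2s3y, a translation initiation factor, and Kdm5d, a histone demethylase, were higher in the numerator pool at 2.10 ± 0.33 and 0.80 ± 0.08. Another Y-linked gene, Zfy1, had 0.06 ± 0.08. The pools thus differed in markers of sex as well as in genotype.

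Crystallins, the structural proteins of the lens, made up 5 of the 9 higher genes. Cryba1 was at 1.21 ± 0.01, Crygf at 0.98 ± 0.07, Cryaa at 0.95 ± 0.12, Cryge at 0.87 ± 0.06 and Cryga at 0.80 ± 0.05. The gamma crystallins are close copies of one another, and probes may not tell them apart. The other higher genes were S100a9, a calcium-binding protein of neutrophils and other myeloid cells, at 0.74 ± 0.08, and Aldoc, the brain form of aldolase in glycolysis, at 0.66 ± 0.07. The rule itself demands that all 10 keep their sign on all 4 arrays, and without that demand the counts were also 9 and 1. With 1 orientation turned neither direction held a gene past the rule.

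**Figure D2:**
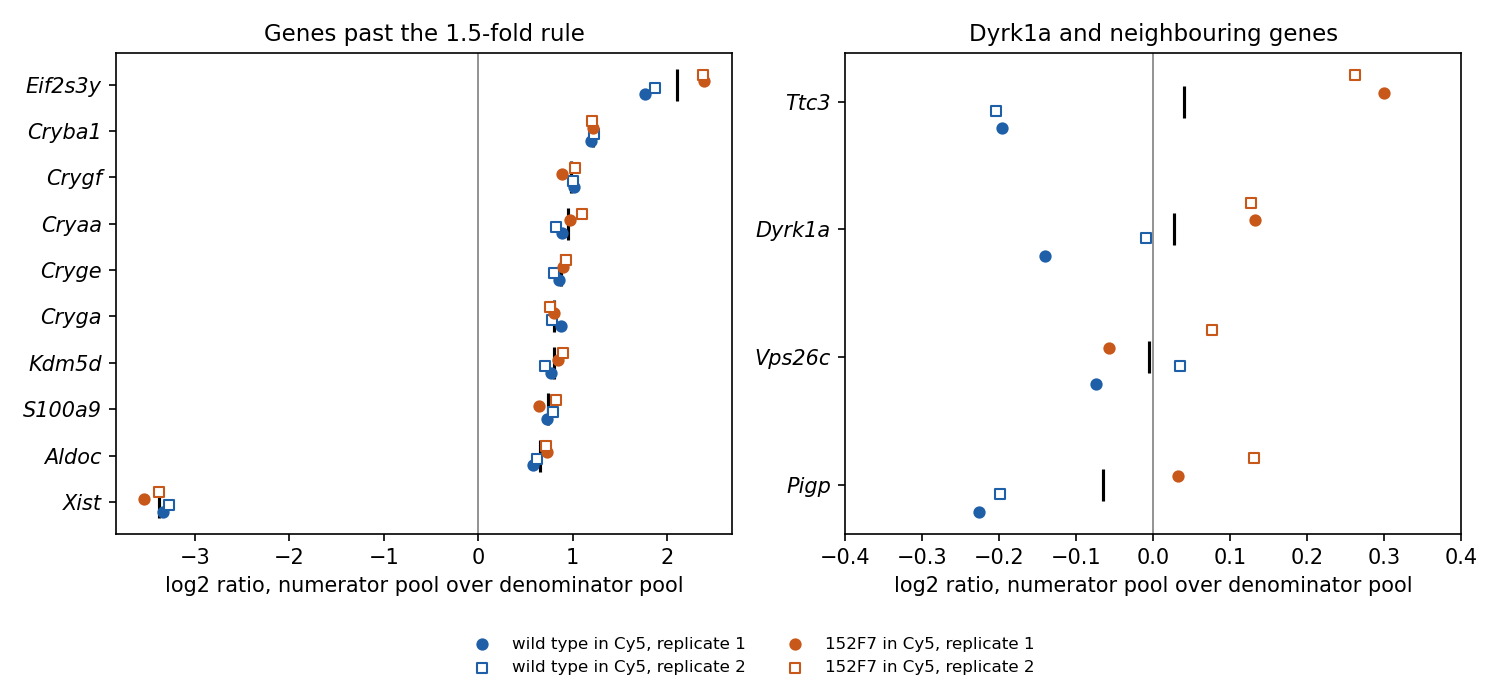
Log2 ratio of the numerator over the denominator pool (x axis) on each of 4 arrays, with the mean as a black bar, for the 10 genes past the 1.5-fold rule (left) and for Dyrk1a and its neighbours (right, another scale). Xist lies near -3.38 in both orientations and Eif2s3y at 1.82 with wild type in Cy5 and 2.38 with 152F7 in Cy5, while the arrays of Ttc3 lie below 0 with wild type in Cy5 and above 0 with 152F7 in Cy5.

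At the looser threshold of 1.06-fold, 896 genes were higher in the numerator pool and 523 lower, against totals of 77 and 63 in the noise contrasts. The share of noise was fixed by the choice of this threshold and is not a result. The contrast between dye orientations, which is the turned reading, held more genes at this threshold, 1370 and 702. Among the 45 gene lists, 14 had a median above the central 95% of random lists and 7 below it, where chance gives 1.12 at each end for independent lists. The noise contrasts put 3 lists above and 5 below, and 2 above and 1 below, with medians of at most 0.037 in size. Of the 21 lists outside, 15 had a larger median than that. The 6 that did not were REST partners and SWI/SNF, axon guidance, Notch, ventral telencephalon, cell cycle and ribosomal proteins, whose shifts are thus of the size that noise gave in some list. In every alternative setting fixed before the data were examined, the turned reading not among them, 9 of the 21 stayed outside the random range. These were eye, sex chromosome genes, red cells, mesenchyme, endothelium, REST targets, axon guidance, oxidative phosphorylation and histones. The other 12 entered it in at least 1. The settings include each dye orientation alone, where the dye effect does not cancel and shifts the random lists as well. The sex chromosome list holds 4 measured genes that go opposite ways, with 2 higher and 1 lower past the 1.5-fold rule. Its median was 0.43 and its mean -0.10, so its place above the range gives no direction. The counts of list members below use the looser threshold.

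Lists of eye, red cell, mesenchyme, endothelium and choroid plexus genes lay higher in the numerator pool. In the eye list 8 of 9 measured genes were higher at the looser threshold (median 0.41 ± 0.04), the crystallin Crygd among them at 0.50 ± 0.07. Of 10 genes of embryonic red cells 6 were higher (median 0.12 ± 0.02, and 0.060 without the noisiest 25% of probes), with the alpha-type globins Hba-x at 0.29 ± 0.26, Hba-a1 at 0.23 ± 0.10 and Hba-a2 at 0.19 ± 0.11, which share sequence, and Alas2, which starts haem synthesis in red cells, at 0.20 ± 0.04. Of 21 genes of pericytes, meninges and mesenchyme 9 were higher and 1 lower (median 0.09 ± 0.02, and 0.052 with the probe nearest to 0 per gene), led by the matrix genes Dcn at 0.43 ± 0.06, Col1a1 at 0.34 ± 0.05, Col5a1 at 0.29 ± 0.08 and Postn at 0.29 ± 0.02. Of 17 endothelial genes 5 were higher and 0 lower (median 0.06 ± 0.04, and 0.11 with 152F7 in Cy5 alone), among them Kdr, a receptor for VEGF, at 0.24 ± 0.04 and Mfsd2a, a lipid transporter of the blood-brain barrier, at 0.26 ± 0.09. Of 18 genes of the dorsal midline and choroid plexus 5 were higher and 1 lower (median 0.04 ± 0.02), with Ttr, the thyroid hormone carrier made by choroid plexus, at 0.34 ± 0.12 and the potassium channel subunit Kcne2 at 0.34 ± 0.06. This list lay inside the random range with 152F7 in Cy5 alone (0.054, 91.9th percentile) and without the noisiest 25% of probes (0.041, 96.5th percentile).

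Some lists of neuronal genes lay higher in the numerator pool and others did not. The synapse list (26 measured genes, 2 higher and 0 lower, median 0.02, 91.7th percentile) and the list of Cajal-Retzius cells, early neurons of the cortical surface (11 genes, 1 higher and 1 lower, median 0.02, 77.1st percentile), lay inside the random range. Of 18 cortical neuron genes 5 were higher and 0 lower (median 0.08 ± 0.02), with the transcription factors Nhlh1 at 0.23 ± 0.15, Nfib at 0.16 ± 0.05 and Neurod1 at 0.10 ± 0.03, and Mapt, which encodes the microtubule protein tau, at 0.16 ± 0.08. Of 19 pan-neuronal genes 3 were higher and 0 lower (median 0.05 ± 0.03), with the neurofilament genes Nefm at 0.33 ± 0.09 and Nefl at 0.29 ± 0.11. With the probe nearest to 0 per gene the pan-neuronal median was 0.014, at the 83.3rd percentile and inside the random range. With 152F7 in Cy5 alone the cortical neuron and pan-neuronal medians, 0.056 and 0.055, were also inside it, at the 92.6th and 91.9th percentiles. They exceed the upper bounds of 0.0337 and 0.0335 that hold for the mean of all arrays, but those bounds do not apply here. A single orientation keeps the dye effect, which shifts the random lists as well. Of 28 targets of the repressor REST, 4 of them also in the pan-neuronal list, 5 were higher and 0 lower (median 0.05 ± 0.04), including the synaptotagmin gene Syt7 at 0.21 ± 0.15 and Bsn, a scaffold of the presynaptic terminal, at 0.14 ± 0.08. Rest itself had -0.02 ± 0.06 with probes of both signs. Of 28 genes for REST partners and the SWI/SNF chromatin remodelling complex 3 were higher and 0 lower (median 0.04 ± 0.04, above 0 on 3 of 4 arrays), such as the histone demethylase gene Kdm1a at 0.11 ± 0.04, and with 152F7 in Cy5 alone this median was 0.019, at the 53.4th percentile. Of 45 genes of neurite growth and axon guidance 12 were higher and 0 lower (median 0.04 ± 0.02), with the semaphorin receptors Nrp2 at 0.22 ± 0.11 and Plxna4 at 0.20 ± 0.09, the guidance ligand Slit2 at 0.17 ± 0.09 and Tiam2, an activator of Rac, at 0.25 ± 0.21. The axon guidance median was 0.020 with the probe nearest to 0, and it lay inside the random range, at the 96.7th percentile, when random lists were matched on gene length.

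Of 25 genes of the ventral telencephalon, which gives rise to interneurons and the striatum, 2 were higher and 1 lower (median 0.03 ± 0.03, above 0 on 2 of 4 arrays). Penk, an opioid peptide precursor, was at 0.22 ± 0.07, and the patterning factor Gsx2 at -0.11 ± 0.04. This list lay inside the random range in several alternatives, among them wild type in Cy5 alone (-0.034), the probe nearest to 0 (0.0093, 77.2nd percentile), and leaving out replicate 1 or 2 of wild type in Cy5 or replicate 2 of 152F7 in Cy5 (93.1st, 96.7th and 92.2nd percentiles). Of 19 Notch pathway genes 4 were higher and 0 lower (median 0.03 ± 0.03), with the receptors Notch3 at 0.23 ± 0.18 and Notch1 at 0.16 ± 0.17. The Notch median over all arrays lay at the 97.6th percentile, and at the 96.2nd when random lists were matched on the SD between arrays. It was inside the random range without replicate 1 of wild type in Cy5 (0.012, 72.2nd percentile), without replicate 2 of either orientation (96.6th with wild type and 94.6th with 152F7 in Cy5), with 152F7 in Cy5 alone (0.019, 52.0th percentile) and with the probe nearest to 0 (0.021, 92.5th percentile). Of 10 hedgehog pathway genes 2 were higher and 0 lower (median 0.06 ± 0.04), Gas1, a co-receptor, at 0.12 ± 0.09 and Sufu, an inhibitor of the pathway's Gli factors, at 0.09 ± 0.04. The hedgehog median lay inside the random range with wild type in Cy5 alone (0.044, 96.2nd percentile) and without replicate 1 of that orientation (0.046, 96.8th percentile).

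Histone genes were lower in the numerator pool. Of 21 genes of core histones, the proteins that package DNA, 14 were lower and 0 higher at the looser threshold (median -0.22 ± 0.04, below 0 on all 4 arrays). H3c1 was at -0.46 ± 0.48, H4c6 at -0.45 ± 0.23, H4c1 at -0.44 ± 0.15 and H4c14 at -0.43 ± 0.06. Histone genes are near-identical copies, so single members are uncertain. Of 84 genes of oxidative phosphorylation, the mitochondrial route to ATP, 18 were lower and 0 higher (median -0.06 ± 0.02), with the respiratory chain subunits Cox7a2 at -0.22 ± 0.01 and Ndufa5 at -0.15 ± 0.02. Of 35 genes of the proteasome, which degrades ubiquitin-tagged proteins, 5 were lower and 0 higher (median -0.04 ± 0.04, below 0 on 3 of 4 arrays), with Psma1 at -0.23 ± 0.08. The proteasome median depended on the orientation, at -0.015 with wild type in Cy5 alone (40.3rd percentile, inside the random range) and -0.094 with 152F7 in Cy5 alone, and was -0.034 in the turned reading (0.06th percentile). Of 74 ribosomal protein genes 4 were lower and 1 higher (median -0.02 ± 0.01), with Rpl7 at -0.12 ± 0.08. The ribosomal median lay at the 6.84th percentile when random lists were matched on gene length, and with wild type in Cy5 alone at the 14.0th (-0.024). Of 16 clustered protocadherins, adhesion proteins of neurons with close copies, 5 were lower and 1 higher (median -0.05 ± 0.03), with Pcdhb22 at -0.16 ± 0.08. The protocadherin median was -0.076 without replicate 2 of wild type in Cy5, -0.11 in that orientation alone, -0.027 without the noisiest 25% of probes (6.85th percentile, inside the random range) and 0.070 (99.6th percentile) in the turned reading.

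Cell cycle genes lay slightly lower in the numerator pool, and not in the same way on all arrays. Of 38 genes 5 were lower and 1 higher (median -0.03 ± 0.04, below 0 on 3 of 4 arrays, with -0.061 for wild type in Cy5 alone and 0.011, at the 34.9th percentile, for 152F7 in Cy5 alone). Top2a, a topoisomerase of dividing cells, was at -0.20 ± 0.14, the replication licensing inhibitor Gmnn at -0.16 ± 0.15 and the mitotic kinase gene Cdk1 at -0.14 ± 0.06, while Ccnd2, a cyclin of the G1 phase, was at 0.26 ± 0.10. Of 14 cell cycle inhibitors 0 passed the looser threshold (median -0.04 ± 0.02, below 0 on 3 of 4 arrays). The inhibitor median lay inside the random range with either orientation alone (-0.015 at the 42.6th percentile with wild type and -0.030 at the 5.69th with 152F7 in Cy5), without replicate 1 of either orientation (-0.032 for both, 3.91st and 5th percentiles), without the noisiest 25% of probes (-0.020, 10.2nd percentile) and with the probe nearest to 0 (-0.026, 2.67th percentile).

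The other 24 lists had medians between -0.02 and 0.03, inside the random range. Of 21 radial glia genes, the neural stem cells of this stage, 4 were higher and 1 lower (median 0.01 ± 0.03), with the patterning factor Lhx2 at 0.28 ± 0.12. Of 14 genes of intermediate progenitors 2 were higher and 0 lower, with Neurog2, a driver of neuronal fate, at 0.09 ± 0.06. Of 50 mouse orthologues of genes of the human Down syndrome chromosome 5 were higher and 2 lower (median 0.02 ± 0.02), among them the adhesion gene Dscam at 0.21 ± 0.07. Of 19 genes for splicing factors and other substrates of DYRK1A 3 were higher and 2 lower. Of 14 genes of the calcineurin and NFAT pathway 1 was higher, the calcineurin regulator Rcan2 at 0.19 ± 0.03. Of 15 p53 and cell death genes 4 were lower and 0 higher, with Trp53inp1 at -0.25 ± 0.12. Of 28 Wnt pathway genes 6 were higher and 1 lower, with the receptor gene Fzd9 at 0.25 ± 0.12 and the secreted inhibitor gene Dkk1 at -0.14 ± 0.06. Of 13 genes of microglia and macrophages 2 were higher, with Lyz2, the lysozyme of myeloid cells, at 0.57 ± 0.07, and of 39 olfactory receptor genes 0 passed in either direction.

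**Figure D3:**
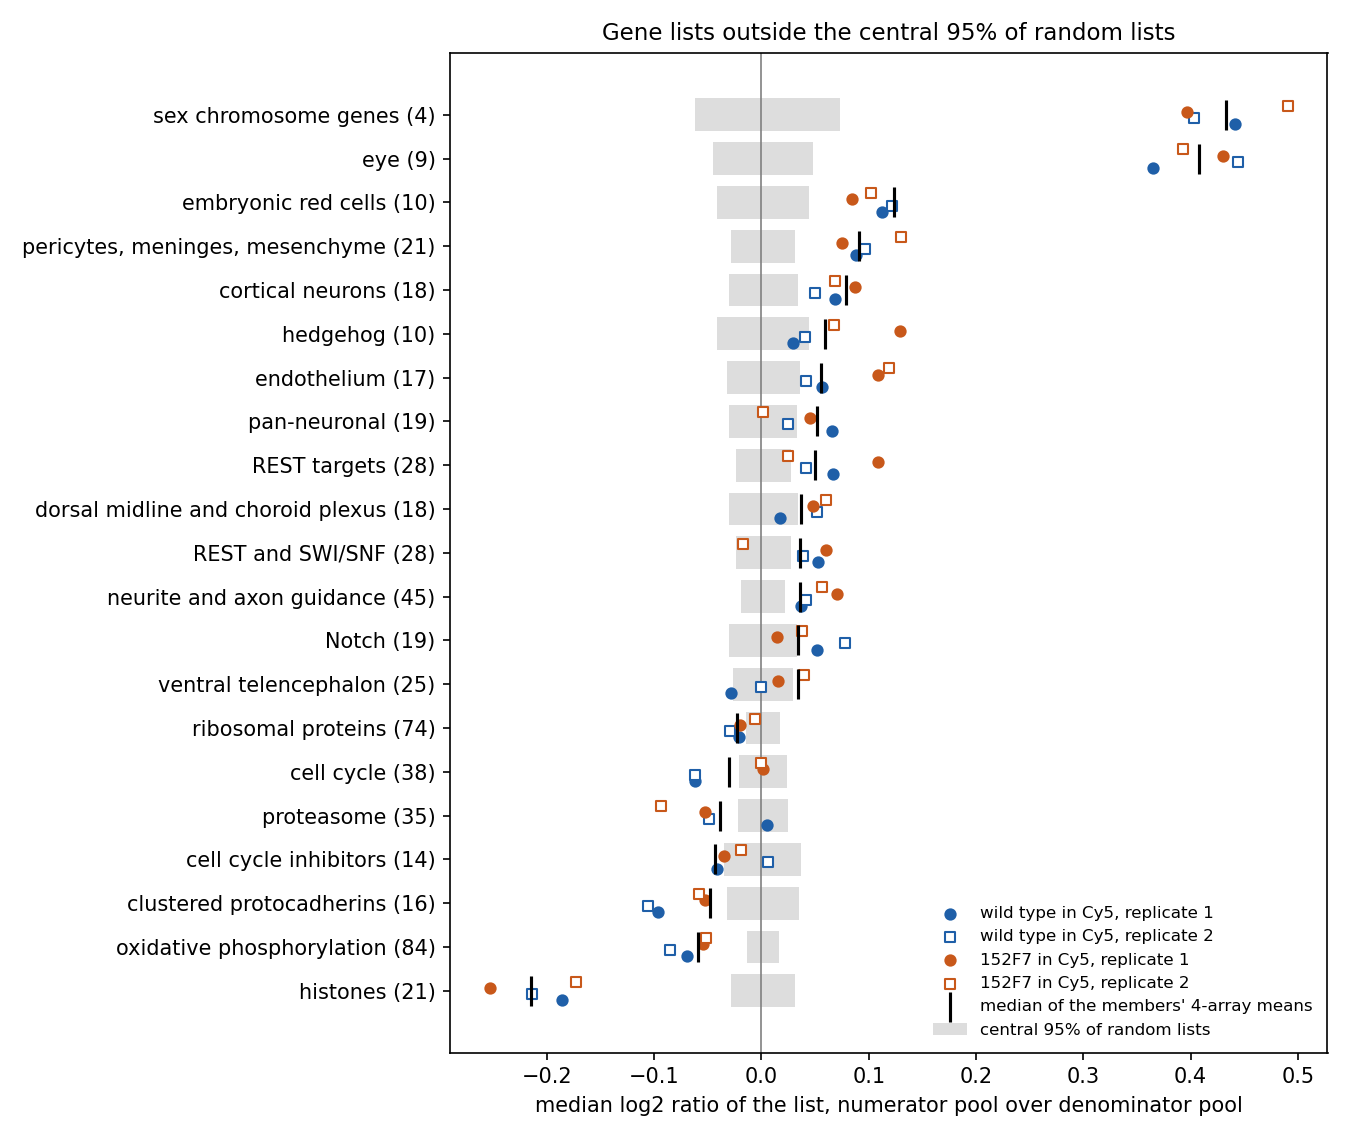
Median log2 ratio of each list outside the random range (x axis) on each of 4 arrays, with the median of the members' means as a black bar, the number of measured genes in brackets and the central 95% of random lists as a grey bar. Eye genes lie near 0.41 and histones near -0.22 on every array, whereas the cell cycle list separates by dye orientation.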

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

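The tests in this part were chosen after the results were seen. Dyrk1a, Ttc3 and Pigp stood out because both arrays of one dye orientation lay below 0 and both arrays of the other above 0. The mean with 152F7 in Cy5 minus the mean with wild type in Cy5 was 0.20 for Dyrk1a, 0.48 for Ttc3 and 0.29 for Pigp, and 0.24 for the median of the list of Dyrk1a and its neighbours. These differences between orientations were not tested. The dye contrast, used from here on, is this difference divided by 2, and is 0.10, 0.24 and 0.15 for the 3 genes. Outside the genes, 117 spots without a gene symbol in the annotation had a dye contrast of at least 1 log2 unit in size, from -3.96 to -1.06, while their mean over all 4 arrays was at most 0.24 in size. Of 17767 spots with a symbol 0 did so, and the largest reached 0.59. Spots without a symbol fell into bands of the dye contrast, with 29 spots around -3.80, 60 around -2.13, 29 around -1.34 and 31 around 0.63, and they enter the correlations over all spots. Control spots with a fixed ratio between the dyes would reverse in this way if the ratios run one way, and would keep their sign under Cy5 over Cy3. Whether these spots are such controls was not tested.

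The weighed pattern is the sign of the difference between the pools across dye orientations. The reading of each value as Cy5 over Cy3 is argued against by the probes of one gene, which correlated at 0.0973 across genes in the turned mean. The reading as a ratio that runs one way on all arrays has the higher correlation of 0.421, with intervals that do not overlap. Under the Cy5 over Cy3 reading, Xist, at -3.30 with wild type in Cy5 and -3.45 with 152F7 in Cy5, would need the pool in Cy3 to be rich in female tissue for either genotype, although each genotype is 1 pool. Eif2s3y, at 1.82 and 2.38, and Cryba1, at 1.21 in both, also kept their sign. The Cy5 over Cy3 reading belongs to whole arrays, so the probe correlations argue against it for Dyrk1a, Ttc3 and Pigp as well. The turned values of these 3 genes would nonetheless all be higher in 152F7, as an added copy of the segment could give. If the ratios run the same way on all arrays, a difference between the pools keeps its sign in both orientations. With wild type in Cy5 the means were -0.075 for Dyrk1a, -0.20 for Ttc3 and -0.213 for Pigp. With 152F7 in Cy5 they were 0.13, 0.281 and 0.0815. Under that reading the change of sign argues against a difference between the pools as the source of the split in these 3 genes. The split then goes with the dye orientation. Whether it comes from a dye effect of their probes or from another part of the labelling was not tested.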

How the results depend on the processing

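The turned reading, first planned as the main one, became an alternative after seeing the data. The matching on gene length was chosen after seeing the data and before its own outcome was seen. The other alternatives were planned. No paired analysis was possible because the comparison rests on 1 pool per genotype and has no test. Named genes past the 1.5-fold rule kept their sign in each alternative that gave them a value, except the turned reading. Xist, Cryge and S100a9 had no value without the noisiest 25% of probes. Cryge, at 0.52 with the probe nearest to 0, and Aldoc, at 0.52 with at least 1 value per orientation, then lay under 1.5-fold. With the probe nearest to 0, Cryaa was at 0.61 and Xist at -1.06. The causes of the differences below were not tested unless stated. Signal over background, which limits weak spots, is unknown.

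Counts of genes higher and lower, 9 and 1 in the main result, were 2 higher at 2-fold, 33 and 16 at the lower fold that was planned, and 896 and 523 at the threshold from noise. They were 14 and 12 with 152F7 in Cy5 alone and 20 and 8 for natural logs. Counted as probes and not as genes, 13 were higher and 4 lower, the lower ones including the 3 probes of Xist. Genes lower numbered 4 with at least 1 value per orientation, 2 with wild type in Cy5 alone and 0 without the noisiest 25% of probes. They numbered 1 to 6 as each array was left out, 6 without replicate 2 of 152F7 in Cy5. Lists above the random range numbered 8 with 152F7 in Cy5 alone, where the dye effect does not cancel, against 14.

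With the probe nearest to 0, medians were 0.050 for cortical neurons, 0.014 for pan-neuronal genes, 0.35 for eye, 0.020 for axon guidance and 0.052 for mesenchyme. Without the noisiest 25% they were 0.46 for eye, -0.020 for cell cycle inhibitors, 0.058 for axon guidance, 0.060 for red cells and 0.80 for sex chromosome genes. With wild type in Cy5 alone the ventral telencephalon turned to -0.034, and medians were 0.058 for cortical neurons, -0.015 for inhibitors, -0.015 for the proteasome, -0.075 for oxidative phosphorylation and -0.11 for protocadherins. With 152F7 in Cy5 alone the cell cycle turned to 0.011, and medians were 0.056 for cortical neurons, 0.054 for axon guidance, 0.11 for endothelium and -0.094 for the proteasome. Natural logs scale every value by one factor and gave 0.11 for cortical neurons, 0.59 for eye, 0.051 for axon guidance, 0.18 for red cells, 0.13 for mesenchyme, 0.62 for sex chromosome genes, -0.033 for ribosomal proteins, -0.085 for oxidative phosphorylation and -0.31 for histones. Leaving out each array gave 0.059 to 0.076 for cortical neurons, -0.076 (without replicate 2 of wild type in Cy5) to -0.061 for protocadherins, 0.012 (without replicate 1 of wild type in Cy5) to 0.034 for Notch, 0.11 to 0.14 for red cells, -0.034 to -0.018 for ribosomal proteins and -0.25 to -0.19 for histones.

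The turned reading gave 0 genes higher and 0 lower at 1.5-fold, 8 and 12 at the lower fold, 1370 and 702 at the threshold from noise, 3 lists above and 3 below the random range, and 0.15 for Pigp. Cryba1 (-0.0018), Crygf (-0.028), Cryga (-0.023) and S100a9 (-0.013) changed sign. So did the cell cycle (0.035), REST and SWI/SNF (-0.0021), Notch (-0.015), red cells (-0.0086), ribosomal proteins (0.0095), oxidative phosphorylation (0.014) and protocadherins (0.070). Other medians were 0.039 for cortical neurons, 0.010 for pan-neuronal genes, 0.0070 for the dorsal midline, 0.012 for eye, -0.010 for inhibitors, 0.0042 for axon guidance, 0.0017 for endothelium, 0.0059 for mesenchyme, 0.011 for sex chromosome genes, -0.034 for the proteasome and -0.028 for histones.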

Other observations

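The genes of this paragraph were chosen after their values were seen. The tests of the next 2 paragraphs were all added after the patterns were seen, and the 3 on gene length and the 1 on variant histones were set before their own outcomes were seen. Single genes outside the fixed lists, picked for their values and not as groups, included the crystallins Crybb3 at 0.49 ± 0.07, Cryba4 at 0.50 ± 0.16 and Cryba2 at 0.36 ± 0.05, and Mip, the water channel of lens fibres, at 0.28 ± 0.10. S100a8, the partner of S100a9, was at 0.31 ± 0.08. Among genes of basement membrane proteins, the nidogen genes Nid1 and Nid2 were at 0.29 ± 0.13 and 0.23 ± 0.13, and the laminin chains Lamc1 and Lamb1 at 0.24 ± 0.04 and 0.24 ± 0.18. The linker histone genes H1f1, H1f3 and H1f4 were at -0.29 ± 0.11, -0.27 ± 0.06 and -0.33 ± 0.19. The X-linked histone demethylase gene Kdm6a, which escapes X inactivation, was at -0.27 ± 0.14. Of 3 probes of the X-linked Eif2s3x, 2 were lower, at -0.28 and -0.56, and 1 was higher, at 1.09, so this gene has no direction here.

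Crystallins were higher in the numerator pool, with a median of 0.65 over 6 measured genes of the eye list. Labelling and hybridisation noise is argued against, since the larger median of these genes in the noise contrasts was 0.017. Eye tissue in the dissected telencephalon of one pool is a candidate source. The other 3 measured genes of the eye list, the pigment cell genes Pmel at 0.28 and Dct at 0.25 and Mitf at -0.03, had a median at the 99.99th percentile of random lists, though Mitf did not share the direction. An effect of the genotype stays open as well, since each genotype is 1 pool.

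Histone genes were lower in the numerator pool, and long genes tended to be higher in it, with a Spearman correlation of 0.167 between gene length and mean ratio across 11765 genes, which are not independent replicates. A trend with gene length as the whole cause is argued against, since against random lists matched on length histones and oxidative phosphorylation both lay at percentile 0 and cortical neurons at percentile 100. Length here is that of the gene and not of its transcript, so a trend with transcript length was not tested. Polyadenylated variant histones had a median of -0.050 ± 0.046 over 7 genes, of which 0 passed the looser threshold. On the arrays it was 0.008 and 0.018 with wild type in Cy5 and -0.069 and -0.064 with 152F7 in Cy5. The variants' median was nearer to 0 than that of the replication-dependent histones at -0.22. Unlike priming of messages without a poly(A) tail could give this. Fewer cells in S phase could too, since the variants do not depend on replication. The comparison therefore cannot tell these apart, and either may account for the histones. For S phase, 13 DNA replication genes had a median of -0.040 ± 0.051, at the 1.74th percentile of random lists. The arrays split by dye orientation, at -0.079 and -0.065 with wild type in Cy5 and at 0.022 and 0.007 with 152F7 in Cy5. The SD thus mostly holds a dye effect, which cancels in the mean. The median goes the way that fewer cells in S phase would. How far it should fall for that cause is not known here, so the value decides neither way. A stricter bound, used at first, had counted against S phase and was dropped after the value was seen, because replication genes stay expressed outside S phase. An effect of the genotype was not tested apart from these.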
